A study of Mus musculus with 6 samples.

How the data were processed

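Gene expression was measured on Affymetrix arrays in Treg cells sorted from spleen and lymph nodes of mice, 3 arrays labelled Gata3-sufficient and 3 labelled Gata3-deficient. Total RNA was extracted with Trizol and 6 ug was made into biotin-labelled cRNA, per the labels' protocols. The authors summarised the probes of each array to log2 intensities by RMA, per the submitters' processing notes, which give no version. RMA corrects background, quantile normalizes the arrays and summarises probes. The deposited table holds 1 log2 value for each of 22690 probe sets on each of 6 arrays, and its columns were matched to samples by sample name. The log2 scale was taken from the range of the values. No scanner files were used here, so background levels and saturation could not be read, and no hybridisation date or batch was given in the sources used here. Groups were taken from the array titles.

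Probe sets were named through the platform's annotation. It listed 21084 of the probe sets, 20393 with 1 gene and 691 with several, and 1606 were not listed. The Entrez identifiers of 20364 matched a gene table of assembly GRCm38.p6, used for names and gene order only, and 0 symbols changed. No genome was used, so the place of a probe set within a gene was not analysed here. Probe sets with several genes or none were left out of the gene comparison. Where a gene had several probe sets (4958 of 12394 genes), the one with the highest mean over the 6 arrays stood for it. No filter on dim probe sets was applied.

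Groups were compared in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with an intensity trend), as the difference of arrays labelled Gata3-deficient minus arrays labelled Gata3-sufficient. Tests were two-sided, and p values were adjusted over all genes by the Benjamini-Hochberg method with a threshold of 0.05. Errors are SDs over the 3 arrays of a group or limma's moderated standard errors of the log2 change, unless marked otherwise. The log2 change is a difference of mean log2 intensities, and folds are computed from it. Gene lists were tested with camera (preset correlation 0.01), adjusted over the 36 lists with at least 5 measured members, and again with an estimated correlation and with fry. Of 620 listed genes 532 were measured. Members of each list were also adjusted over the list alone, and lists share some members. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

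The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Gata3 and Foxp3, the 12 higher and 12 lower genes with the largest changes past the threshold, up to 4 members of each described list with the smallest p, and any list member past the threshold. Predicted genes and clones were left out of naming, which passed over 8 genes past the threshold. A few further genes, named in the closing section, were chosen after their values were seen. The replicate numbers in the titles are not stated to pair mice, so the groups were compared unpaired.

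The alternatives were the replicate number as a block, no intensity trend, robust variance estimation, dim probe sets left out (mean below the 40th percentile, 5.25), renewed quantile normalization, median centring, array quality weights, other choices of probe set per gene, other thresholds, and each array left out in turn. The fit was tested on simulated data with the 12394 genes' own means and spread, 3 arrays against 3 and 200 genes changed. It called 61.2% of genes changed by a log2 value of 0.5, 94.0% of those changed by 1 and 100% of those changed by 2, with 4.49% of calls false and 0 of the wrong sign. With no gene changed it called 0. Each simulated gene was drawn independently, so variation shared by genes within an array was not simulated, and these rates do not cover it.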

Results

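Regulatory T (Treg) cells are CD4 T cells that restrain immune responses and depend on the transcription factor Foxp3. The cells studied here were sorted from mouse spleen and lymph nodes as CD4+CD25+YFP+ cells, where YFP is fused to a Cre recombinase expressed from the Foxp3 locus. Cre deletes a floxed (loxP-flanked) part of Gata3, which encodes a transcription factor of T cell development and of type 2 helper T cells. Mice with both Gata3 alleles floxed gave the 3 arrays labelled Gata3-deficient. Mice with 1 floxed and 1 intact allele, which also carried the Cre, gave the 3 arrays labelled Gata3-sufficient, titled WT. The series' design text gives 3 mice per group. Each array holds log2 intensities of 22690 Affymetrix probe sets, from which 12394 genes were compared. Array medians lay between 6.06 and 6.11. The number of arrays limits the precision of every value below. The first principal component held 35.2% of the variance and separated the 2 groups. The second set replicate 1 of the arrays labelled Gata3-deficient, at 0.65, apart from replicates 2 and 3 of that group, at -0.43 and -0.53.

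The comparison asked which transcripts differ in Treg cells when Gata3 is deleted, and Gata3 itself came first. The single Gata3 probe set read higher, not lower, in the arrays labelled Gata3-deficient. It read 9.57, 9.41 and 9.47 in the arrays labelled Gata3-sufficient and 9.83, 9.98 and 9.71 in those labelled Gata3-deficient. The group means were 9.48 ± 0.08 and 9.84 ± 0.14 (SD, n = 3 each), a 1.28-fold difference (log2 change 0.35 ± 0.07, SE, adjusted p = 0.0387 by limma). The probe set of the targeted gene thus showed no loss of transcript, and every direction below rests on the labels alone. Which part of Gata3 was deleted is not given in the sources used here, and a probe set outside that part checks nothing about the labels. The call was lost without the intensity trend (adjusted p = 0.15). It was also lost without sufficient replicate 2 (log2 change 0.32, adjusted p = 0.183) or 3 (0.35, 0.0984) and without deficient replicate 1 (0.36, 0.0753) or 2 (0.28, 0.132). Foxp3, on whose reporter the cells were sorted, lay among the dim probe sets, at 3.90 ± 0.05 and 3.94 ± 0.12 (SD, n = 3 each). Its log2 change was 0.04 ± 0.10 (SE, adjusted p = 0.91), and no difference in Foxp3 was detectable with this probe set.

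Gzmb, Gzma, Cd22 and Cxcl10 were among the largest increases in the arrays labelled Gata3-deficient, and Tlr7, Il7r, Sox4, Ifng and Satb1 were among the largest decreases. Gzmb, which encodes the granule protease granzyme B, rose 2.73-fold (log2 change 1.45 ± 0.11, SE, n = 3 and 3, adjusted p = 0.00037). Gzma, the gene of granzyme A, rose 1.98-fold (0.99 ± 0.17). Cd22, an inhibitory co-receptor best known from B cells, rose 2.22-fold (1.15 ± 0.11). Cxcl10, an interferon-inducible chemokine, rose 2.05-fold (1.03 ± 0.12). Tlr7, a receptor for single-stranded RNA, had the largest decrease of the named genes, at 2.86-fold lower (log2 change -1.52 ± 0.11, adjusted p = 0.00037). In all, 179 genes were higher and 95 lower in the arrays labelled Gata3-deficient at an adjusted p under 0.05. That direction rests on the labels alone, since the Gata3 probe set showed no decrease.

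The 12 genes with the largest increase were completed by Lyz1, Baiap3, Ppic, Actg2, Rnf32, Cpq, Hfe and Serpinc1, with log2 changes from 0.83 to 1.44. Lyz1, a lysozyme gene, had the largest of these (1.44 ± 0.31, SE), but on a probe set that can read near-identical copies. With such probe sets left out the Lyz1 change was -0.0092 and the call was lost, but the 1 probe set then left is dim (mean 3.78), so this does not decide whether Lyz1 changed. The 12 genes with the largest decrease also held Tktl1, Chdh, Il7r, Cnn3, Sox4, Sytl2, Ifng, Satb1, Penk, Phlpp1 and Nrp1. Tktl1, a transketolase-like gene on a dim probe set (as is Hfe), fell by 1.32 on the log2 scale, and Chdh, the gene of choline dehydrogenase, by 1.30. Il7r, the interleukin 7 receptor alpha chain, fell by 1.08 (11.62 ± 0.13 against 10.55 ± 0.45, SD, n = 3 each). Sytl2, a synaptotagmin-like gene of vesicle transport, fell by 1.01 with the smallest adjusted p of these genes (9.07e-05). Sox4, a transcription factor gene, fell by 1.02 on the brightest of its 6 probe sets. Its other probe set that is not dim (mean 6.07) changed by -0.16 ± 0.12 (SE), and the dim ones by -0.63 to -0.07. The size of the Sox4 decrease thus rests on 1 probe set. Ifng, the gene of interferon gamma, fell by 0.98. In all 24 genes the values of the 2 groups did not overlap, which holds for all 274 genes past the threshold. Over all 12394 genes 19.8% did not overlap, against 10% by chance.

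**Figure D1:**
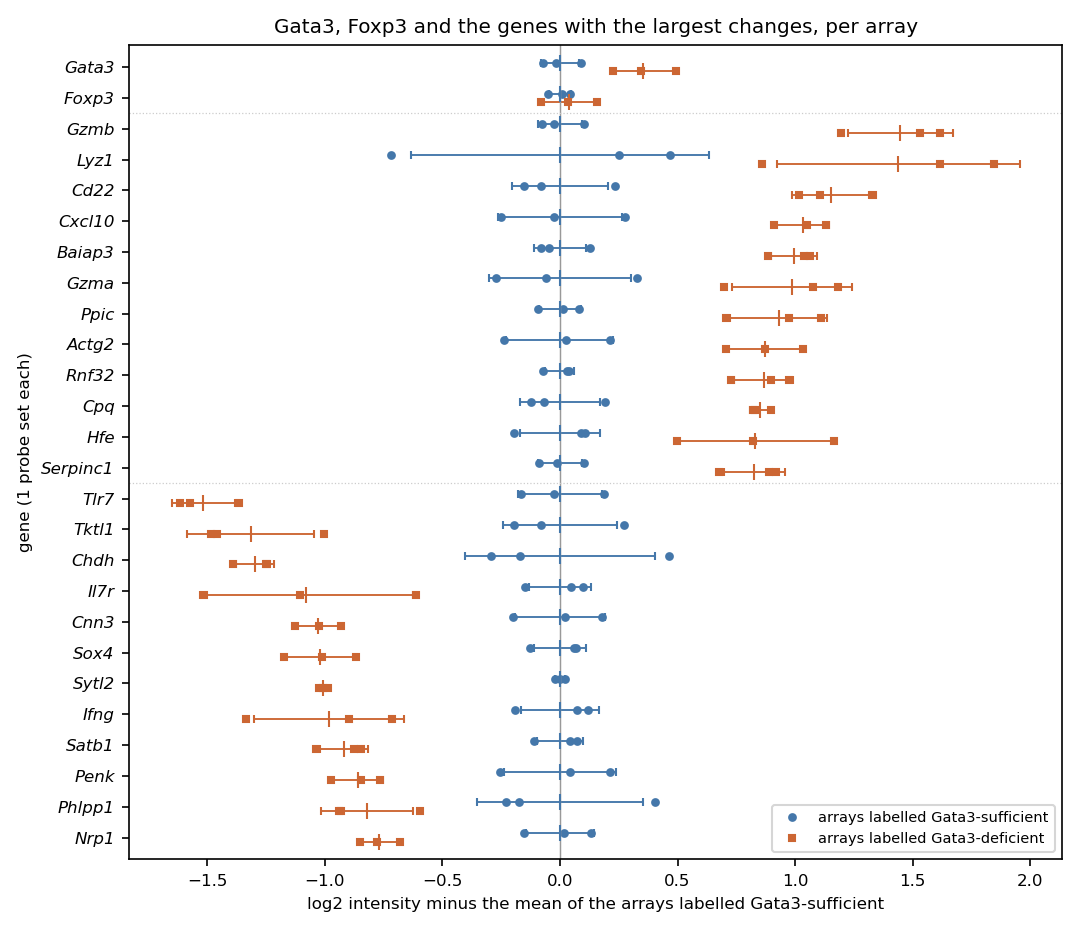
Log2 intensity of Gata3, Foxp3 and the 12 genes with the largest increase and 12 with the largest decrease past the threshold, for each array, minus the mean of the 3 arrays labelled Gata3-sufficient (horizontal axis; one gene per line). Points are arrays, ticks group means and bars 1 SD; Gata3 lies higher in the 3 arrays labelled Gata3-deficient, the Foxp3 groups overlap, and Gzmb (1.45) and Tlr7 (-1.52) bound the gene changes.

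Most changes were small. The median size among the 274 genes was a log2 change of 0.43, or 1.35-fold, and only 4 of the higher and 7 of the lower genes reached a 2-fold change. At an unadjusted p under 0.05 there were 1789 genes, where 619.7 were expected by chance. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1, so the calls rest on limma's estimate of the spread across genes. Without limma's intensity trend 31 genes were higher and 23 lower, 53 of them among the 274, and 18 of the 24 named genes stayed past the threshold. Of 35 further genes named below as members of lists, all past the threshold, 3 (Top2a, S100a4 and S100a6) kept their calls without the trend. Leaving out sufficient replicate 2 left 38 and 24, deficient replicate 2 left 35 and 27, deficient replicate 3 left 51 and 50, and sufficient replicate 3 left 125 and 54. With each array left out in turn, 18 of the 24 named genes passed in all 6 fits. Lyz1 and Gzma passed in 2 of 6 fits, Hfe in 1, Il7r and Phlpp1 in 3 and Ifng in 5, with adjusted p up to 0.159, 0.111, 0.181, 0.0793, 0.127 and 0.0738. Those losses came without sufficient replicate 1 (Hfe), sufficient replicate 2 (all 6 genes), sufficient replicate 3 (Lyz1, Gzma, Hfe and Il7r), deficient replicate 1 (Hfe and Phlpp1), deficient replicate 2 (Lyz1, Gzma, Il7r and Phlpp1) or deficient replicate 3 (Lyz1, Gzma and Hfe).

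Of 36 gene lists, 12 shifted against all other genes, 8 upwards and 4 downwards in the arrays labelled Gata3-deficient (camera, adjusted p under 0.05 over the lists). With an estimated correlation between genes camera passed 0 lists, and 3 had an unadjusted p under 0.05. The rotation test fry, which asks whether a list moves on balance in one direction, passed 2 lists, effector cytoskeleton and migration and naive or resting T cell.

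The cell cycle list shifted upwards. Of 37 measured genes of S phase and mitosis, 35 had a positive change, with a median of 0.21 (camera adjusted p = 2.04e-11; adjusted p = 0.362 with an estimated correlation). Over all genes tested 6 rose and 0 fell, and 14 rose when adjusted over the list alone. Birc5 (0.79), Top2a (0.71), Mki67 (0.68), Ccnb2 (0.63), Rrm2 (0.56) and Aurkb (0.52) passed, with standard errors from 0.09 to 0.14. Mki67 encodes the proliferation marker Ki-67, and Top2a the topoisomerase that untangles replicated DNA. Top2a passed in all 6 fits with 1 array left out, Mki67 in 4, Birc5 and Rrm2 in 3, Ccnb2 in 2 and Aurkb, a dim probe set (mean 4.15), in 1. Without the intensity trend Top2a alone of the 6 kept its call (adjusted p = 0.0409), and the others had 0.0629 to 0.1. The mean shift of the list was 0.21, 0.29 and 0.35 in deficient replicates 1, 2 and 3. A combined score of 29 myeloid and neutrophil genes shifted in the same arrays, by 0.11, 0.33 and 0.40.

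The effector cytoskeleton and migration list shifted upwards as well. Of 19 measured members 7 rose and 0 fell over all genes tested, and 10 rose and 1 fell when adjusted over the list alone. The median was 0.19 (camera adjusted p = 4.32e-07; adjusted p = 0.166 with an estimated correlation; fry adjusted p = 0.0137). S100a4 (0.82 ± 0.09, SE) and S100a6 (0.71 ± 0.06), calcium-binding proteins of activated and migrating cells, rose and passed in all 6 fits with 1 array left out. Lgals3 (0.59) and Lgals1 (0.49), which encode galectins, and Vim (0.41), the gene of the intermediate filament vimentin, passed in 3 of 6 fits. Anxa2 (0.49) and Ahnak (0.25) passed in 1 of 6. The list shifted by 0.24, 0.24 and 0.23 in deficient replicates 1, 2 and 3, beside the unequal myeloid and neutrophil score above.

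The naive or resting T cell list shifted downwards. Satb1, a chromatin organiser of thymocytes and naive T cells, fell by 0.92 on the log2 scale and passed in all 6 fits with 1 array left out. Il7r is given above. Bach2, a repressor of effector differentiation, fell by 0.36, and Txk, a kinase of T cell receptor signalling, by 0.32, passing in 3 and 1 of 6 fits. Over all genes tested 4 of 15 measured members fell and 0 rose, and 8 fell and 2 rose when adjusted over the list alone. The median was -0.15 (camera adjusted p = 7.41e-05; adjusted p = 0.166 with an estimated correlation; fry adjusted p = 0.0137).

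The Treg signature list was divided. Of 29 measured members 3 rose and 3 fell, and 11 rose and 5 fell when adjusted over the list alone (median 0.05; camera adjusted p = 0.167). Gzmb (above), Socs2 (0.65 ± 0.09, SE), a suppressor of cytokine signalling, and Tnfrsf4 (0.32 ± 0.05), the receptor OX40, rose. Penk, which encodes the precursor of enkephalins, fell by 0.86. Nrp1, the receptor neuropilin 1 found on thymus-derived Treg cells, fell by 0.77, from 11.03 ± 0.14 to 10.26 ± 0.09 (SD, n = 3 each). Klrg1, a receptor of terminally differentiated lymphocytes, fell by 0.58. Tnfrsf4 and Klrg1 passed in 3 of 6 fits with 1 array left out. Ctla4 had a change of 0.22 that did not pass (adjusted p = 0.0531).

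Among helper T cell lists, the Th17 list shifted upwards with 2 of 16 genes past the threshold, Th1 genes went both ways, and none of the Th2 genes passed. In the Th17 list Ccr6 (0.57 ± 0.11, SE), a chemokine receptor, and Rora (0.49 ± 0.09), a nuclear receptor of Th17 cells, rose, with 4 higher when adjusted over the list alone. The list's median was 0.14 (camera adjusted p = 0.000312; adjusted p = 0.37 with an estimated correlation; fry adjusted p = 0.0809). Il17a had a change of 0.45 and Il6st of 0.22, neither past the threshold. Ccr6 passed in 2 and Rora in 1 of 6 fits with 1 array left out. In the Th1 list Gzmb and Gzma rose while Ifng fell and Tbx21, the gene of the Th1 transcription factor T-bet, fell by 0.63. That list's median was -0.05 and its mean 0.04, camera placed it downwards and fry upwards, and it did not pass (camera adjusted p = 0.827). It had 4 members higher and 2 lower when adjusted over the list alone. Tbx21 passed in 4 of 6 fits. Of 24 measured Th2 genes 0 passed in limma over all genes tested, 1 was lower when adjusted over the list alone, and 2 were higher and 4 lower at an unadjusted p under 0.05, with a median of -0.0031 (camera adjusted p = 0.631). The nearest were Il17rb (-0.63, adjusted p = 0.0587), Ecm1 (-0.26), the dim Epas1 (0.39) and Gfi1 (-0.32).

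The list of genes that respond to interleukin 2 through STAT5 shifted upwards, with 3 of 17 past the threshold. Socs2, Tnfrsf4 and Lta (0.38 ± 0.06, SE), the gene of lymphotoxin alpha, passed, with 6 higher when adjusted over the list alone. The median was 0.16 (camera adjusted p = 7.41e-05; adjusted p = 0.37 with an estimated correlation; fry adjusted p = 0.0849). Lta passed in 4 of 6 fits with 1 array left out, and Cish had a change of 0.30 that did not pass. In the TGF-beta response list Nrp1 fell, 2 members rose and 4 fell when adjusted over the list alone, and the median was -0.10 over 13 genes (camera adjusted p = 0.0101; adjusted p = 0.362 with an estimated correlation). Ctsl, a cathepsin gene, had a change of -0.58 that did not pass.

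A further 4 lists shifted with 0 members past limma's threshold over all genes. Oxidative phosphorylation genes had a positive change in 24 of 26 members, with a median of 0.08 (camera adjusted p = 3.63e-05; adjusted p = 0.362 with an estimated correlation), with 5 higher when adjusted over the list alone and 10 at an unadjusted p under 0.05. Atp5c1 (0.16) and Cox5b (0.13) had the smallest p. Cholesterol biosynthesis genes had a median of 0.14 (0.013; adjusted p = 0.665 with an estimated correlation) and 0 members past the threshold adjusted over the list alone, with 2 higher at an unadjusted p under 0.05. Its mean shifts overlapped between groups, at -0.22, 0.10 and 0.12 in sufficient and 0.18, 0.11 and 0.18 in deficient replicates 1, 2 and 3. That list's call was lost without sufficient replicate 1 (adjusted p = 0.563) and with array quality weights (0.0702). Heat shock genes, which encode chaperones, had a median of -0.25 over 11 members (0.000796; adjusted p = 0.413 with an estimated correlation), with 1 lower when adjusted over the list alone and 4 at an unadjusted p under 0.05. Hsph1 (-0.64), Dnaja1 (-0.38) and Hsp90aa1 (-0.25) did not pass. The heat shock list's mean shifts overlapped between groups, at -0.18, 0.25 and -0.07 in sufficient and -0.07, -0.44 and -0.42 in deficient replicates 1, 2 and 3. Interferon-stimulated genes had a median of -0.15 over 25 members (0.00242; adjusted p = 0.665 with an estimated correlation), with 6 lower when adjusted over the list alone, and 7 lower and 1 higher at an unadjusted p under 0.05. Oasl1 (-0.57), Usp18 (-0.44) and Ifit2 (-0.24) did not pass. The interferon list's shifts overlapped as well, at 0.19, -0.14 and -0.05 against -0.01, -0.19 and -0.27. The interferon list's call was lost without sufficient replicate 1 or deficient replicate 3 (adjusted p up to 0.128).

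Markers of other leukocytes were read for cells that a sort can carry over. Myeloid and dendritic cell genes had a median of 0.16 over 17 members (camera adjusted p = 0.0133; adjusted p = 0.447 with an estimated correlation). Lyz1 rose, with 2 higher when adjusted over the list alone, while Lyz2 (1.02 ± 0.26, SE) and Tyrobp (0.47 ± 0.17) did not pass. Neutrophil, mast cell and basophil genes had a median of 0.16 over 12 members (0.0204; adjusted p = 0.362 with an estimated correlation), with 0 past limma's threshold, also adjusted over the list alone, and 2 higher at an unadjusted p under 0.05. S100a9 (1.10) and, on dim probe sets, Ngp (0.74) and S100a8 (0.64) did not pass. The myeloid call was lost without deficient replicate 3 (adjusted p = 0.0983) and without the probe sets that can read near-identical copies (0.0518), and the neutrophil call without sufficient replicate 3 or deficient replicate 2 (adjusted p up to 0.176). In the B cell list Cd22 and Cd74 (0.42 ± 0.08), the chaperone of class II histocompatibility molecules, rose among 15 members, with 3 higher when adjusted over the list alone, and the list did not pass (median 0.0031, camera adjusted p = 0.249) except with dim probe sets left out (0.00991). Cd74 passed in 1 of 6 fits with 1 array left out. H2-Aa (0.54) and Cd79b (0.23) did not pass. The other 24 lists, including the Treg signature, Th1, Th2 and B cell lists, had camera adjusted p from 0.0519 to 0.995. With all 6 arrays, 3 of these besides the B cell list passed in some settings. The NK and innate lymphoid cell list passed downwards without the intensity trend (0.0328), with array quality weights (0.0379) and with the mean of all probe sets per gene (0.0221). The NF-kB and TNF receptor response list passed upwards with array quality weights (0.0125) and without the probe sets that can read near-identical copies (0.0428), and the glycolysis list upwards with the mean of all probe sets (0.0473). With 1 array left out these 3 lists passed in 3, 2 and 1 of 6 fits.

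**Figure D2:**
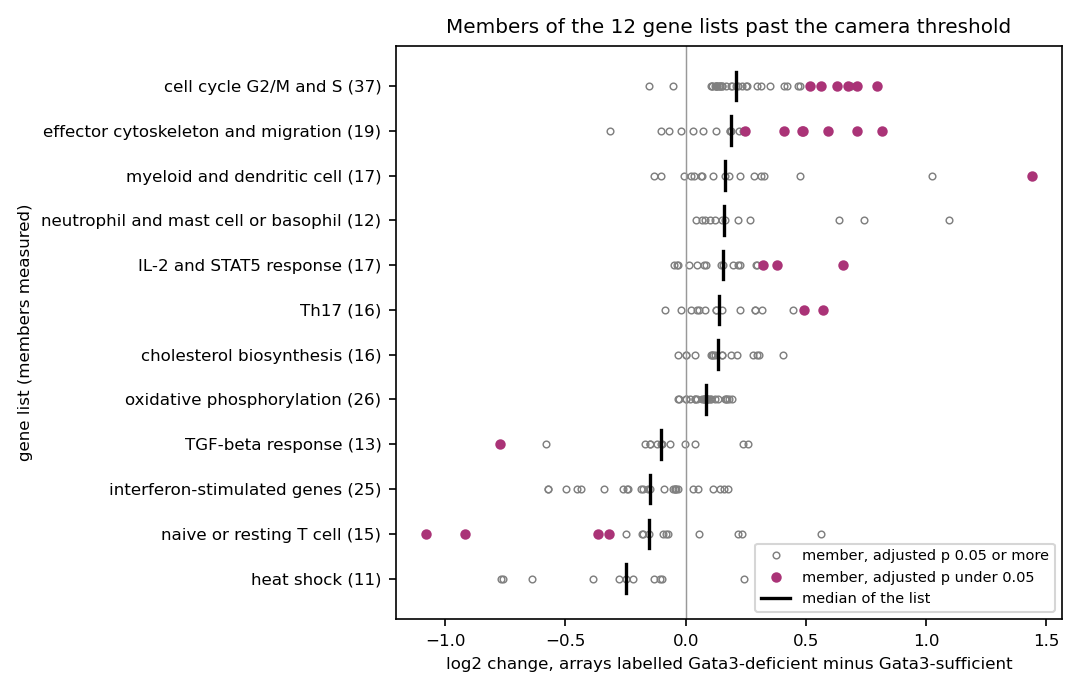
Log2 change of each measured member (points) of the 12 gene lists past the camera threshold, arrays labelled Gata3-deficient minus arrays labelled Gata3-sufficient, with each list's median as a black bar and the number of members in brackets. Filled points are genes past the threshold over all genes tested; medians run from 0.21 for the cell cycle list to -0.25 for the heat shock list.

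Members of further lists also passed, while those lists did not. Cxcr5 (0.54 ± 0.08, SE), which directs cells to B cell follicles, rose, as did Ccr6, while Cxcr6 fell by 0.47; in the homing list 2 of 23 were higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.548). Among genes of the follicular helper list Sh2d1a, the gene of the adaptor SAP, fell by 0.35. Of the antigen receptor signalling genes, Fyn (0.32) and Cd6 (0.26) rose and Txk fell, and 3 of 19 were higher and 4 lower when adjusted over the list alone (0.772). Myb (0.43), a transcription factor gene, rose within the T lineage list, in which Satb1 fell and Gata3 read higher. Of that list's 23 members 3 were higher and 8 lower when adjusted over the list alone, and its shift was downwards and did not pass (0.0969). Dusp1 (0.46), an immediate early phosphatase gene, and Pmaip1 (0.57), the gene of the apoptosis protein NOXA, rose. Slc2a3, a glucose transporter gene, fell by 0.28, and Cd7 by 0.38. Tnfsf8 (0.36) and Tnfsf11 (0.42), ligands of the TNF family, rose in the list of genes lower in Treg than in conventional CD4 T cells, in which Satb1, Bach2, Il7r and Ifng fell. That list's median was 0.08 and its mean -0.04, and camera placed it upwards and fry downwards (camera adjusted p = 0.864). With 1 array left out, Dusp1 passed in all 6 fits, Cxcr5, Sh2d1a and Pmaip1 in 5, Tnfsf8 and Tnfsf11 in 4, Fyn and Myb in 3, Slc2a3 in 2 and Cxcr6, Cd6 and Cd7 in 1, and all 12 lost their calls without the intensity trend (adjusted p from 0.0714 to 0.171).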

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

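The signal below was examined outside the planned gene comparison, and no test of its origin was made. Probe sets with no gene or with several genes in the annotation took no part in the gene comparison. Of 2297 such probe sets, 29 passed an adjusted p of 0.05 in limma over all probe sets, 12 higher and 17 lower in the arrays labelled Gata3-deficient. They were set apart here because they carry a difference between groups in data the comparison did not use. Over all 22690 probe sets 310 passed, and 0 of the 64 control probe sets did, of which 8 had an unadjusted p under 0.05.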

How the results depend on the processing

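The direction of all 274 calls held under renewed quantile normalization and median centring, and it turned for 1 call without _x_at probe sets and 2 with the most variable probe set. That direction also held with the replicate block, array weights and each left-out array. Those settings test it little, because the block leaves the differences unchanged and the groups of all 274 genes did not overlap. The counts of genes higher and lower were 31 and 23 without the intensity trend, 400 and 185 with array quality weights, 343 and 182 at an adjusted p of 0.1, and 4 and 7 with a 2-fold change required. With each array left out in turn the counts ran from 35 to 165 genes higher and from 24 to 106 lower. The calls shared with the 274 numbered 53 without the trend. The cause was not tested.

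The replicate number as a block gave 234 genes higher and 134 lower, sharing 253 of the 274 calls. Deviations from the group means correlated at 0.04, -0.02 and 0.07 between same-numbered arrays and at -0.06 to 0.02 between arrays of different numbers. The values 0.04 and 0.07 were the largest of all pairs, so these correlations do not decide whether the numbers mark pairs. The groups were compared unpaired because no source states that the numbers pair mice.

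The Gata3 change stayed at 0.35 without the trend but lost its call (adjusted p = 0.15), and ran from 0.28 to 0.42 with an array left out. The Foxp3 change, without a call in any setting, ran from -0.022 to 0.096 with an array left out, and with dim probe sets left out Foxp3 has no value. Lyz1 turned to -0.0092 without _x_at probe sets, on a dim probe set. Changes near 0 also turned with an array left out for Eif2s3y (-0.0092 to 0.044), Ctss (-0.033 to 0.027), Cst3 (-0.013 to 0.13) and Ighm (-0.040 to 0.0039). Among named genes, calls were lost 130 times and gained 13 times with an array left out, and lost 68 times and gained 33 times over the other settings. Lists past the threshold numbered 12, with 11 to 14 when an array was left out, 0 with an estimated correlation and 2 by fry. Probe sets near the dimmest values, such as Foxp3, limit what can be read.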

Other observations

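The TNF family, class II, Gata3, myeloid, dim probe set and Cd22 tests in this part, and the splits for the gene counts, were chosen after the values were seen.

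Several ligands of the TNF superfamily, membrane and secreted proteins by which lymphocytes signal to neighbours, were higher in the arrays labelled Gata3-deficient. Besides Lta, Tnfsf8 and Tnfsf11, these were Tnfsf14 (log2 change 0.64 ± 0.08, SE), the ligand LIGHT, and Tnfsf13b (0.72 ± 0.15), the B cell survival factor BAFF, both named after their values were seen. A first test, on 14 ligand genes picked by eye, had 5 higher and 0 lower (Fisher's exact p = 1.07e-06), and a scan of all families then replaced it. Of 7 measured Tnfsf genes 4 rose and 0 fell, where 0.101 would be higher by chance. Among 413 gene families defined by symbol, with 5 or more measured genes each, this was the 1 family past the one-sided Fisher's exact test for genes higher (adjusted p = 0.000588). For genes lower 0 families passed that test, and 9 had an unadjusted p under 0.05. Fisher's test takes genes as independent draws, but all calls come from the same 6 arrays. The Tnfsf genes were also noticed in these data before the scan. The expected 0.101 counts all 12394 genes, 4504 of them dim, while 10 of the 274 calls were dim. The adjusted p of 0.000588 therefore does not exclude chance. Tnfsf14 passed in all 6 fits with 1 array left out and without the intensity trend, and Tnfsf13b in 1 fit and not without the trend (adjusted p = 0.118). In deficient replicates 1, 2 and 3 Tnfsf14 (7.29, 7.41 and 7.43) and Tnfsf13b (6.06, 6.16 and 6.59) climbed in the order of the myeloid and neutrophil score (0.11, 0.33 and 0.40), while Lta, Tnfsf8 and Tnfsf11 went in the opposite order, and other cells in the sort were not tested for these genes.

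H2-Oa (0.56 ± 0.07, SE) and H2-DMa (0.54 ± 0.09), of the peptide-loading machinery of class II histocompatibility molecules, rose beside Cd74. They were named after their values were seen. In a family of 11 class II pathway genes, picked by eye, 3 rose and 0 fell (Fisher's exact p = 0.000449). Multiplied by the 413 families scanned above this p is 0.185, so chance membership stays open. H2-DMa read 8.57, 8.73 and 8.84 and H2-Aa 9.04, 9.30 and 9.64 in deficient replicates 1, 2 and 3, the order of the myeloid and neutrophil score, H2-Oa (8.15, 8.12 and 8.27) and Cd74 (7.69, 7.59 and 7.83) did not follow it, and other cells in the sort were not tested for these genes. H2-Oa passed in all 6 fits with 1 array left out and without the intensity trend, and H2-DMa in 3 fits and not without the trend. Cirbp, the gene of a cold-inducible RNA-binding protein, rose by 0.76 ± 0.11 (SE), also named after its value was seen. It passed in 4 of 6 fits and not without the trend, while the heat shock list had a median of -0.25. A probe set shared by Rbm3 and its pseudogene, outside the gene comparison, rose by 0.48 ± 0.05 (SE, limma adjusted p = 0.00311 over all probe sets). It was also named after its value was seen, and the cause of these changes was not tested. Xist lay between 12.78 and 12.93 and the Y-linked Eif2s3y between 2.62 and 2.73 in all 6 arrays. The 3' minus 5' value of the transferrin receptor control, read as a sign of RNA quality, was 1.34, 1.15 and 1.23 in the arrays labelled Gata3-sufficient and 1.40, 1.64 and 1.45 in those labelled Gata3-deficient, without overlap; its gene Tfrc, named after its value was seen, itself rose (0.62 ± 0.06, SE). Those of actin (0.75 to 0.89 against 0.86 to 0.91) and Gapdh (0.38 to 0.55 against 0.48 to 0.52) overlapped, and whether RNA quality affects the comparison was not tested.

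The Gata3 probe set read higher in the arrays labelled Gata3-deficient. Its change of 0.35 ± 0.07 (SE) argues against correct labels together with a probe set that reads only intact transcript. An exchange of all labels between the 2 groups stays open. Of 6 arrays, 0 lay nearer the other group's Gata3 mean. The Gata3 values of the groups did not overlap and each array counts in its own group's mean. That count therefore cannot show whether a single array was out of place. Transcript of the recombined allele may also be read by this probe set, at 1.28-fold the level of the arrays labelled Gata3-sufficient. These cannot be told apart here, because the sources used do not give the deleted part and the probe set's place in the gene was not analysed.

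The cell cycle and effector cytoskeleton lists shifted upwards in arrays that also read higher for myeloid and neutrophil markers, although the sort required CD4, CD25 and YFP. More myeloid cells in the sort would leave little change once the score of 29 such genes (15 of them not dim, 0 in another list) is a covariate. The effector list kept 0.22 ± 0.15 (95% interval, 0.24 without the covariate), so its change did not follow this score. The score was itself higher in every array labelled Gata3-deficient, and 1 of its 29 genes was past the threshold. A noisy score would remove too little, so more myeloid cells are not excluded for the effector list. The cell cycle list had 0.13 ± 0.32 (0.28 without), an interval that holds both values, so myeloid cells and a change within Treg cells cannot be told apart; a first criterion, narrowed after its result was seen, had counted this as fitting myeloid cells. The 27 brighter cell cycle genes had a mean change of 0.28, so the list's shift was not confined to dim probe sets. The SE of that mean, 0.05, was taken over genes and not over arrays. The list's genes varied together (estimated correlation 0.25), so this SE understates the error. Of the 29 score genes, 26 had a positive change. The brightest of them, Ctss (12.22) and Cst3 (9.47), changed by -0.0075 and 0.07. The myeloid share of their signal was not measured, so these values do not decide for or against myeloid cells.

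Cd22 rose although the cells were sorted as CD4 T cells. More B cells in the sort would raise the other B lineage genes with it. The 6 other members of the B cell list that are not dim had a median change of 0.32, against 1.15 for Cd22. The SE of their mean, taken over genes and not over arrays, was 0.14. That median does not lie 2 such SE below 0.58, 0.5 times the Cd22 change. B cells and a change of Cd22 within the sorted cells therefore cannot be told apart by this test. Members went apart. Cd74 changed by 0.42 and the class II genes H2-Aa and H2-Ab1 by 0.54 and 0.45, and Cd79b by 0.23. Ighm, of the highest intensity (12.18), changed by -0.01, Ms4a1 by -0.40 and the dim Cd79a by -0.20. A probe set shared by immunoglobulin kappa genes, outside the gene comparison, fell by 0.58 (limma adjusted p = 0.0489 over all probe sets). A first version of this test, on 11 members without the class II genes and Cd74, had a median of -0.023 and argued against B cells, but 8 of the 11 are dim, and it was replaced.

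Variants carried along with the floxed Gata3 allele could differ between groups and could place changed genes near it. Of the 100 tested genes nearest to Gata3 on its chromosome, 1 (Vim) was past the threshold, where 2.21 were expected. The 95% upper limit of that share is 2.02% of the 273 other genes past the threshold. Changed genes were thus not in excess near Gata3 (Fisher's exact p = 0.728). The planned criterion asked for more changed genes than the 100 could hold, so it decides nothing about linkage. Linked variants that act on distant genes were not tested. When the 6 arrays were split in all 10 ways into 3 and 3, 1 split gave as many genes higher as the 179, as many lower as the 95 and as many lists as the 12, the real one. The highest of the other splits gave 0 genes and 9 lists. With 10 splits the share cannot fall below 0.1, so it could not reach a threshold of 0.05.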
